A study of Mus musculus with 20 samples.

How the data were processed

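Liver RNA of 20 male C57BL/6J mice, an inbred laboratory strain, was measured on 1 array each. Per the labels, 10 mice ate a high-fat diet (HFD) with 45 kcal% of energy as fat for 4 weeks. Another 10 ate that diet with 0.05% of a maple syrup extract, abbreviated MSXH in the labels. Livers were taken on day 30 after a 16 h fast, and the labels call the arrays biological replicates 1 to 10 of each group. The study's protocol also names a low-fat group with 10 kcal% fat and a group given 0.02% extract, which were not analysed here.

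Per the labels' protocols, the authors labelled RNA copies with biotin from 200 ng of total RNA using a 3' IVT kit, which reads mostly the 3' ends of transcripts. The deposited values of 45101 probe sets were taken as log2 levels. They ran from 5.2 to 14.96, and the highest exceeds the natural log (11.09) and the log10 (4.82) of the largest 16-bit scanner value. Background correction, normalization and probe summary are not given in the sources used here. Array medians lay between 6.505 and 6.506. The median over probe sets of the SD between the 20 arrays was 9.33e-06, and 49 probe sets spanned a range above 0.1. Ordinary between-animal variation in RNA is far larger, so the deposited differences are compressed and cannot be read as fold changes. For that reason each difference is given as Hedges' g, the difference of group means divided by the pooled SD and corrected for small samples, with its 95% interval. Raw differences are given on the deposited scale for some genes. Signal over background is not known for these values, and the number of arrays limits the precision.

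Of the probe sets, 64 were controls and were left out of the gene tests. Among the other 45037, the platform annotation used here names 1 gene for 34945, several genes for 932 and none for 9160. Gene numbers of 34741 probe sets were found in the reference gene table, and 0 symbols needed updating. Each of the 18193 named genes was represented by the probe set with the highest mean over the 20 arrays. Genes with a mean below the median of the probe sets (6.505) were removed, which left 11728. Genes without a probe set of their own in that annotation were not used here. No genome was used, so no coordinates are given.

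The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings) on the values as deposited, with Benjamini-Hochberg adjustment and a threshold of adjusted p = 0.05. Gene lists of metabolic pathways, stress responses and cell types were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation as an alternative. Values were multiplied by 1000000 for camera, because its estimate of the correlation floors residual variances at 1e-08 and 86.7% of the genes lay below that. The multiplication was chosen after seeing the data and leaves the preset test as it was. Of 33 lists, 31 had at least 5 members tested. The distance between group means and the first principal component were tested by permuting group labels 100000 times. Named genes were the 6 with the smallest p in each direction where none passed, the 4 members with the smallest p in each list past the threshold, and up to 2 members of other lists at an unadjusted p below 0.05. A fixed set of liver genes was added where measured, and 4 of its 22 members were not used here for lack of a probe set of their own. The groups, tests, lists and this rule were fixed before the data were examined. Alternatives covered scaling between arrays, the filter, the choice of probe set, the variance model, array weights, the replicate number as a block, other tests and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

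The procedure was tested on simulated data for this comparison, over 11728 genes with 200 shifted. The limma test recovered 0.5% of genes shifted by 1 SD, 13% at 1.5 SD, 59% at 2 SD and 97.5% at 3 SD. With no shift it called 0 genes. The simulated genes were drawn independently of each other, so the simulation does not show how the test behaves where genes move together. No pair of arrays held identical values.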

Results

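Liver expression was compared between 10 mice fed a high-fat diet and 10 mice fed the same diet with 0.05% maple syrup extract (MSXH), which addresses the effect of the extract on the liver in high-fat feeding. Each mouse gave 1 array, and 11728 genes were tested. Differences are MSXH minus HFD throughout, in SD units as Hedges' g, because the deposited values are compressed between arrays.

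No single gene differed between the diets past the threshold. With limma, 0 of 11728 genes changed (smallest adjusted p = 0.9998), and 425 genes had an unadjusted p under 0.05. That is 3.62% of genes, 221 higher and 204 lower, where chance gives 5%. A Wilcoxon rank-sum test also called 0 genes, whereas a rank product called 561. That method also called a median of 641 genes when the mice were split at random. The 95% range of g over genes was -0.839 to 0.839. In simulated data with independent genes, the limma test recovered 97.5% of genes shifted by 3 SD but 0.5% of those shifted by 1 SD. In that setting, differences of about 1 SD were not detectable with this number of arrays.

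The genes with the smallest p did not pass. Among those higher in MSXH, Rab11fip5, which encodes a Rab11-binding protein of vesicle recycling, had g = 2.27 (95% interval 1.15 to 3.40, unadjusted p = 0.000151, adjusted p = 0.9998, n = 10 per group). Its mean differed by 6.1e-06 on the deposited scale, and 9 of 10 MSXH mice lay above the HFD median. It is also measured by another probe set, whose difference has the opposite sign. Hils1 had g = 2.03, Tal1, a blood-lineage transcription factor, 1.64, Scai 1.56, 5430440P10Rik 1.53 and Pcp4l1 1.52. Among those lower, Ghitm, a mitochondrial inner membrane protein, had g = -1.77 (95% interval -2.81 to -0.738, unadjusted p = 0.000537), with both of its probe sets lower. Mplkip had g = -1.68, Pafah1b1 -1.66, Smg8 -1.63, Foxh1 -1.55 and Rims3 -1.54. The sign was shared by 1 of 2 probe sets of Mplkip and of Rims3, 3 of 5 of Pafah1b1 and 3 of 4 of Scai. In both groups the means of Rab11fip5 (6.66), Hils1 (6.67), Tal1 (6.61) and Rims3 (6.57) lay near the filter level of 6.505. Those of Pafah1b1 (8.75) and Ghitm (11.09) lay well above it.

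The main spread between mice did not follow the diet. On the compressed deposited scale, the first principal component held 75.1% of the variance. Mt1, a zinc-binding metallothionein, made up 59.4% of that component, Hsd3b5, a male-biased steroid dehydrogenase, 11.2% and Mt2 5.56%. The groups' scores on it did not differ past the threshold (two-sided permutation p = 0.637), nor did the distance between group means (one-sided permutation p = 0.680). With each gene scaled to unit variance the first component held 16.4% of the variance, the second 15.2%, and these p-values were 0.708 and 0.648. For Mt1, g was -0.325 and the lowest and highest mice were 8.09 and 9.76. Mt1, Hsd3b5, Mt2 and the other genes plotted by mouse were chosen for their spread after their values were seen.

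**Figure D1:**
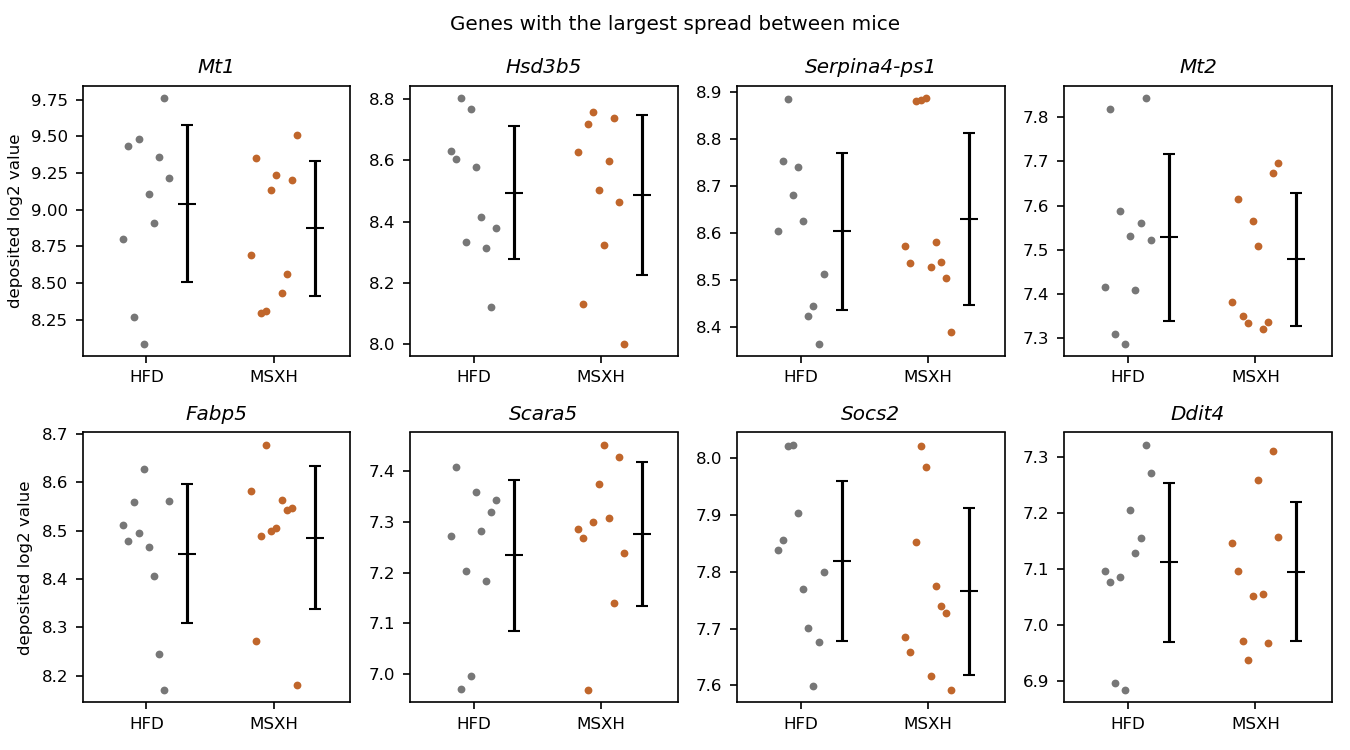
Deposited log2 values (y axis) of the 8 genes with the largest spread between mice, by diet (x axis). Points are single mice (n = 10 per group), and bars give the mean and SD. The groups overlap in each panel, and Mt1 has the largest SD, 0.495.

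Gene lists gave small shifts in a common direction, and 5 of 31 passed the camera threshold at the preset correlation, of which 0 passed with an estimated correlation. Genes of cholesterol synthesis and uptake were higher in MSXH in 18 of 20 members (median g = 0.476, camera adjusted p = 0.000256, but adjusted p = 0.848 with an estimated correlation). Tm7sf2, a sterol reductase, had g = 1.05 (95% interval 0.116 to 1.99), Srebf2, the transcription factor that drives the pathway, 0.965, and Nsdhl 0.823. Ebp, a sterol isomerase, went the other way at -1.04. Cytosolic ribosomal protein genes were higher in 14 of 18 members (median g = 0.652, adjusted p = 0.000256, but adjusted p = 0.848 with an estimated correlation). Rps24 had g = 1.12, Rps9 1.12, Rpl8 0.944 and Rps3 0.872. For Rps9 and Rps3, 2 of 3 probe sets shared that sign.

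Heat shock protein genes were lower in MSXH in 12 of 14 members (median g = -0.582, camera adjusted p = 0.000459, but adjusted p = 0.718 with an estimated correlation). Hspa4 had g = -1.06, Dnajb1 -0.840, Bag3, a co-chaperone, -0.764 and Hspa8 -0.755. For Hspa4, 3 of 4 probe sets shared that sign. Mitochondrial respiratory chain genes were lower in 22 of 24 members (median g = -0.513, adjusted p = 0.000644, but adjusted p = 0.718 with an estimated correlation), and the list had no clear direction when arrays were shifted to the same median (nominally higher, adjusted p = 0.971). Cox6b1 had g = -1.02, Cycs, cytochrome c, -0.795, Ndufs3 -0.749 and Atp5o -0.737. The lowest g of the list was -1.42, for Atp5b, but its unadjusted limma p was 0.766. The 2 can part for genes with very small spread, since g uses the gene's own SD and limma an SD moderated over all genes. Markers of sinusoidal endothelial cells, which line the liver capillaries, were higher in 14 of 15 members (median g = 0.302, adjusted p = 0.0152, but adjusted p = 0.718 with an estimated correlation). Dnase1l3 had g = 0.822, Oit3 0.581, Eng 0.573 and Kdr 0.567.

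None of the members of any list passed, whether adjusted over all genes or adjusted over the list alone (0 of 470 genes, with 15 at an unadjusted p under 0.05). With fry, which asks whether a list moves one way on balance, 0 lists passed, and 50 of 100 splits of the mice, the diet split included, gave at least 5 lists with camera. With arrays shifted to the same median the ribosomal (adjusted p = 0.142) and endothelial (adjusted p = 0.113) calls ended too, and with quantile normalization cholesterol synthesis passed of the 4 of these lists that could be tested, ribosomal proteins not being among them. The endothelial call was also lost without HFD replicate 2, MSXH replicate 7 or MSXH replicate 9, with adjusted p up to 0.0886.

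**Figure D2:**
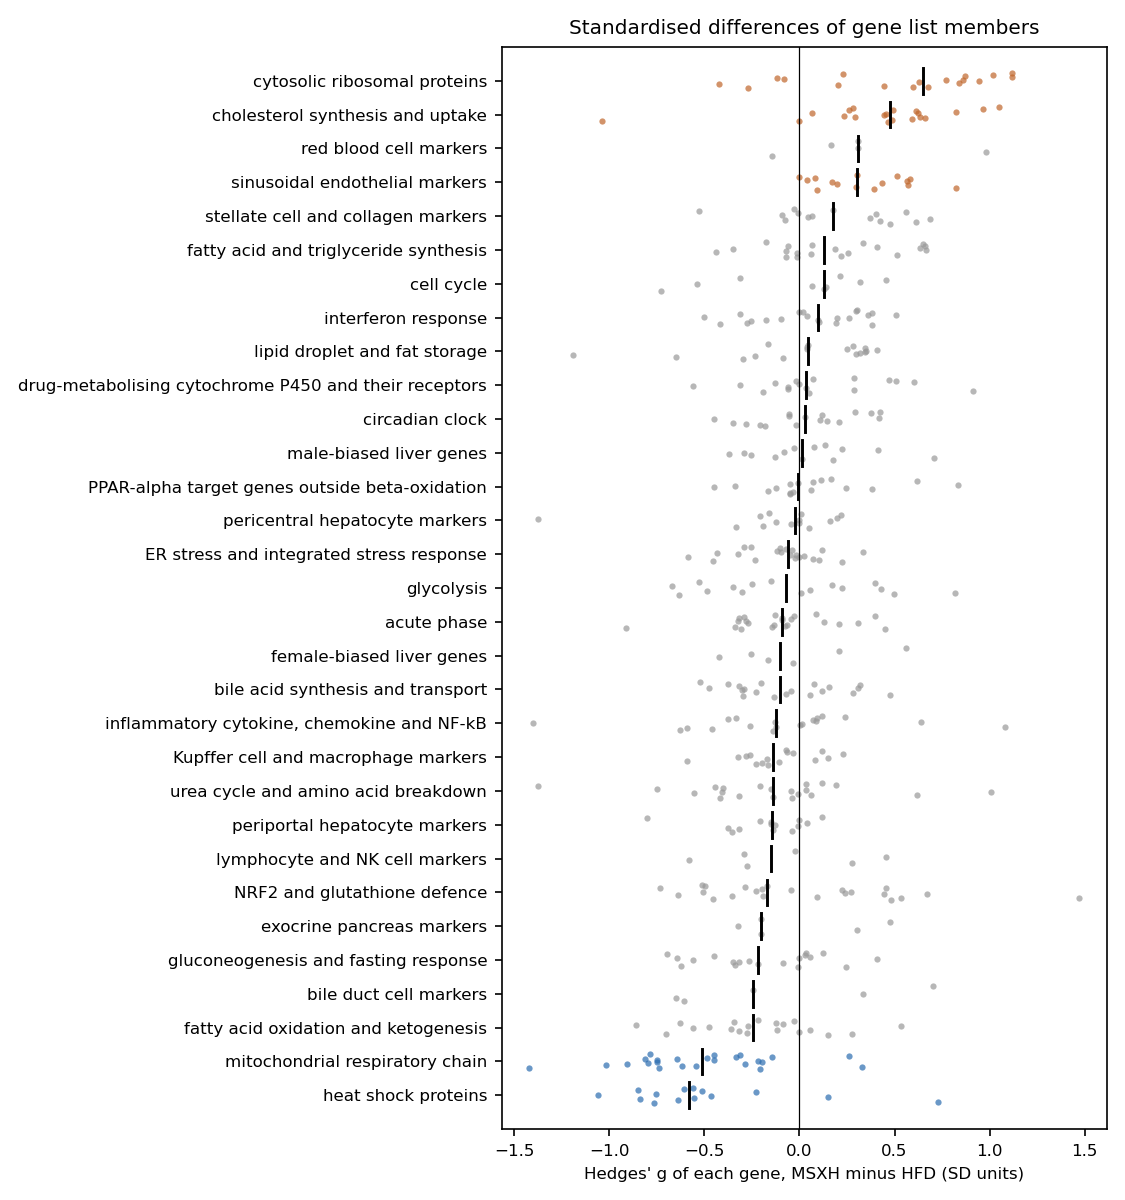
Hedges' g of each gene tested (x axis, SD units, MSXH minus HFD) in the 31 lists (y axis). Black lines are list medians, orange lists were higher and blue lists lower past the camera threshold at the preset correlation, and grey lists did not pass. The medians of the coloured lists run from -0.582 to 0.652, and the respiratory chain list had no clear direction, nominally higher, when arrays were shifted to the same median.

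**Figure D3:**
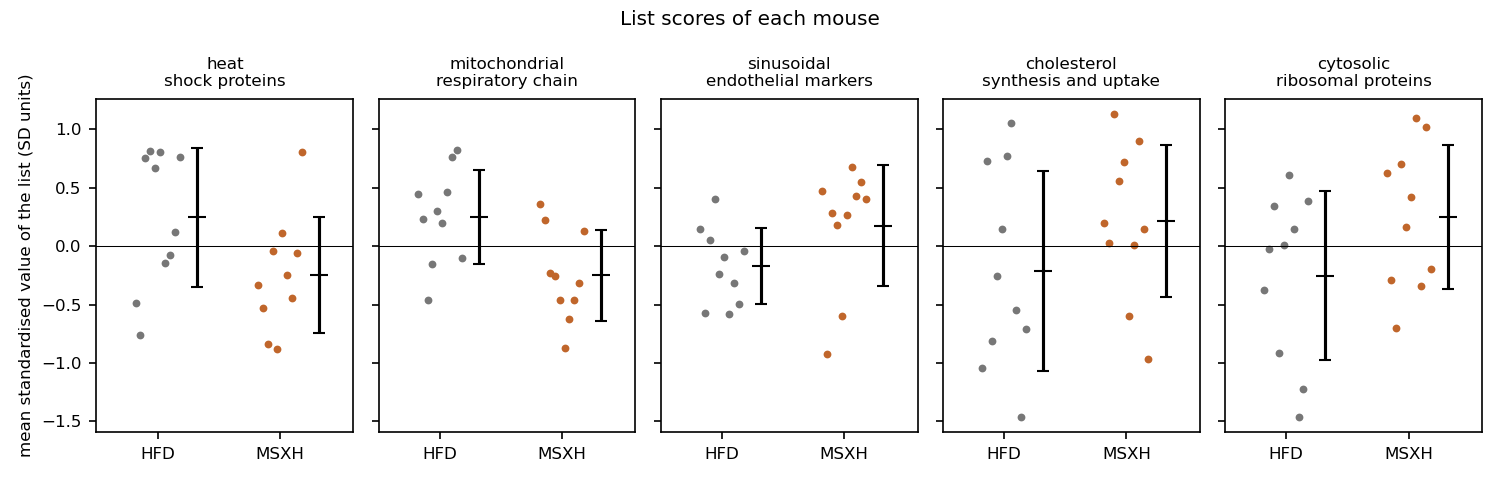
Mean standardised value (y axis, SD units) of the 5 lists past the camera threshold at the preset correlation in each mouse, by diet (x axis). Points are mice (n = 10 per group), and bars give the mean and SD. The groups overlap: 9 of 10 MSXH mice lie below the HFD median for the respiratory chain and for heat shock proteins, and 6 of 10 above it for ribosomal proteins.

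Other metabolic lists did not pass. Fatty acid oxidation and ketogenesis had 16 of 20 members lower (median g = -0.246, adjusted p = 0.238). Fatty acid and triglyceride synthesis had 12 of 20 higher (median g = 0.128, adjusted p = 0.257), with Scd1, the main stearoyl-CoA desaturase, at g = 0.650, Srebf1 at 0.337 and Fasn at 0.189. Gluconeogenesis and the fasting response had 13 of 19 lower (adjusted p = 0.238). Its rate-limiting enzyme gene Pck1 had g = -0.0043 (95% interval -0.881 to 0.872) and G6pc -0.317. Glycolysis had 8 of 16 higher (adjusted p = 0.884), with Pklr at 0.395. Among the other 8 is Pigq (g = -0.251), which the lookup of older symbols put in place of the listed Gpi1 and which was not meant to be tested. For the urea cycle and amino acid breakdown, 14 of 21 members were lower (adjusted p = 0.334). Oat, ornithine aminotransferase, had g = -1.38 and an unadjusted p of 0.00410, and 0 of 10 MSXH mice lay above the HFD median. Glud1 had g = 1.01. Bile acid synthesis and transport had 12 of 20 lower (adjusted p = 0.775), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had g = -0.303 (95% interval -1.18 to 0.578). Targets of the fatty acid receptor PPAR-alpha had 8 of 17 higher (adjusted p = 0.775), with a median slightly below 0 and a camera direction above it. Ppara had g = -0.029, Cpt1a 0.053, with 1 of 3 probe sets of that sign, and Fgf21, a fasting hormone, -0.049. Lipid droplet genes had 11 of 17 higher (adjusted p = 0.990), and Fabp2 had g = -1.19.

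Lists of defence and inflammation did not pass either. Among inflammatory genes 10 of 19 were lower (adjusted p = 0.558). Il1b had g = -1.40 (95% interval -2.38 to -0.425, unadjusted p = 0.00360), Cxcl1, a neutrophil chemokine, 1.08 and Ccl2 -0.140. In both groups the means of Il1b (6.75) and Ccl2 (6.61) lay near the filter level of 6.505, and that of Cxcl1 was 7.53. Acute phase genes were lower in 17 of 23 (adjusted p = 0.597), with Crp at -0.913 and Saa1 at -0.319. Interferon response genes were higher in 13 of 21 (adjusted p = 0.844), and genes of ER stress lower in 16 of 22 (adjusted p = 0.558). NRF2 and glutathione genes were lower in 13 of 23 (adjusted p = 0.992), with a median of -0.173 against a camera direction of higher. Cbr3, a carbonyl reductase, had g = 1.47 and Hmox1 -0.197. Nqo1 lay below the filter and had g = 0.173. The list of drug-metabolising cytochrome P450 genes and their receptors had 10 of 17 members higher (adjusted p = 0.558). The receptors Ahr, Nr1i2, Nr1i3 and Rxra were all among the higher, and the 7 lower members were all P450 genes. Cyp2e1, counted as higher, had g = 3.96e-08. Cyp1b1 had g = 0.915, Cyp3a11 0.602, Cyp2b10 0.286 and Cyp1a1, below the filter, 0.281. The sign was shared by 2 of 3 probe sets of Cyp1b1 and 1 of 3 of Cyp2b10.

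Among markers of other cell types, stellate cell and collagen genes were higher in 10 of 15 (adjusted p = 0.238), red blood cell genes in 4 of 5 (adjusted p = 0.265, Bpgm g = 0.981) and Kupffer cell and macrophage genes in 4 of 16 (adjusted p = 0.558). Periportal hepatocyte markers were lower in 12 of 14 (adjusted p = 0.334) and pericentral markers in 8 of 14 (adjusted p = 0.558). Circadian, cell cycle, male-biased, female-biased, lymphocyte, bile duct and exocrine pancreas lists had adjusted p from 0.872 to 0.992. In 3 of these the median and the camera direction differed in sign: cell cycle (median g = 0.127), female-biased genes (-0.101) and exocrine pancreas (-0.203). The 3' minus 5' actin control, a sign of RNA integrity, had g = 0.491 (two-sided permutation p = 0.270). Of 64 control probe sets, 0 passed the threshold and 2 had an unadjusted p under 0.05. Actb had g = -0.215.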

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

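The tests of list means by permutation were chosen after related results had been seen. The actin covariate and the scaled rank product were also added after seeing the data.

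In 5 of 130 sets of 10 mice, 1 mouse lay far from the others, where chance gives about 5%, or 6.5 sets. The gap to the nearest mouse was 0.540 of the group's range for Tal1 in MSXH (replicate 7, low) and 0.468 for Oat in HFD (replicate 3, low). It was 0.494 for Rps24 in MSXH (replicate 9, high), 0.501 for Rpl8 in HFD (replicate 9, low) and 0.501 for Cyp1a1 in HFD (replicate 2, high). No mouse stood apart in more than 1 of these.

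Shifts of gene lists are the first pattern: of 100 splits of the mice, the diet split included, 50 called at least as many as its 5 lists with camera (highest other split 10), so chance cannot be excluded for that count. With an estimated correlation and with fry, 0 lists passed. Of the other splits, 96 called at least 1 list, with a median of 4. The mean correlation between members of the 5 lists ran from 0.129 (endothelial markers) to 0.580 (cholesterol synthesis), far above the preset 0.01. Genes moving together within a list may be enough for 4 of the lists. Their means gave permutation p = 0.223 for cholesterol synthesis, 0.112 for ribosomal proteins, 0.0890 for endothelial markers and 0.0609 for heat shock proteins. The respiratory chain gave 0.0125 (adjusted p = 0.389 over 31 lists). A difference carried by the actin control is argued against for 2 lists. With that control as a covariate, the respiratory chain kept 120% and ribosomal proteins 143% of their mean standardised difference. Each fit divided by its own residual SD, so these are not shares of the raw mean difference. The control's SD was 5.2e-05 in HFD and 5.3e-05 in MSXH on the compressed scale. How well it tracks RNA integrity here is not known, so RNA integrity as the cause stays open. An effect of the extract on respiratory chain genes stays open as a hypothesis. The call was lost under both changes of scaling. Shifting arrays to the same median moves whole arrays by more than most genes vary, so the loss there decides nothing.

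The 561 genes of the rank product are the second pattern, against 0 with limma. Of 100 splits, 79 called at least as many (highest other split 1290), so chance cannot be excluded. Of the genes called, 95.9% were in the top 10% of spread and 126 were called both higher and lower. With each gene scaled to the same spread the rank product called 0 genes, which is consistent with unequal spread of the probe sets as their source.

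For the 425 genes at an unadjusted p under 0.05, 64 of 100 splits gave as many (highest other split 2758), so chance cannot be excluded. With limma 4 of the other splits called genes past the threshold, up to 777. Such splits can come from a structure among the mice, and what they separate was not tested.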

How the results depend on the processing

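No gene passed in any of 12 alternative limma or Wilcoxon fits or in 20 fits without 1 array. The smallest adjusted p was 0.0765, for Rab11fip5 without MSXH replicate 5. With all 20 arrays, a threshold of adjusted p = 0.1 also gave 0 genes. A fold threshold of 1.5 says nothing here, since the values are compressed. The count at an unadjusted p under 0.05 was 425. It was 46 with arrays shifted to the same median, 126 with quantile normalization, 780 with no filter, 197 with the 75th percentile filter and 875 for each probe set on its own. The last 4 differ in the number tested, 11212, 18193, 6941 and 22519, against 11728. Without 1 array it ran from 318 to 598. The rank product called 561 genes, 333 higher and 354 lower, and 0 once genes were scaled, an alternative added after seeing the data.

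Against 5 lists, 0 passed with an estimated correlation, 0 with fry and 13 with arrays shifted to the same median, 2 of them among the 5. An estimated correlation on values not multiplied, added after seeing the data, called 3, but the variance floor left it up to 0.520 away from the correlation measured in a list. With quantile normalization 1 of 30 lists passed (cholesterol synthesis, adjusted p = 0.00229), and ribosomal proteins had too few varying members to be tested. With arrays shifted to the same median the respiratory chain list was nominally higher (adjusted p = 0.971), which is no evidence of a reversal. Array medians differ by 0.000176, more than the median SD of a gene within groups, 1.48e-05, so that shift moves whole arrays by more than most genes vary. Under it 12 of 57 named genes changed sign, which says nothing of their stability, and 13 of 40 did with quantile normalization. With the actin control as a covariate, added after seeing the data, 7 lists passed. Without 1 array 4 (without MSXH replicate 7) to 9 (without HFD replicate 5) lists passed, and 8 without HFD replicate 3. The cause was not tested for the other changes.

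The labels give no pairing of mice by replicate number, and the values showed no clear one, though a weak pairing cannot be excluded. Deviations of same-numbered mice correlated from -0.136 to 0.373 (mean 0.053, against -0.006 for other numbers). Of 20 arrays, 2 correlated best with their own number. With the replicate number as a block, 0 genes changed, 501 had an unadjusted p under 0.05 and 5 lists passed.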

Other observations

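The pairs of genes below were chosen after the most variable genes had been seen, and their correlations were computed afterwards.

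The genes that varied most between mice did so within both diets. Ranks and shares of spread hold only on the compressed deposited scale, where the median SD of a probe set was 9.33e-06 and that of Mt1 0.495. They cannot be read as shares of the variation in RNA. On that scale the 50 genes with the largest spread held 98.7% of the variance of the genes tested, and Mt1 alone 46.2%. They include Socs2 and Cish, feedback inhibitors induced by growth hormone, Bcl6, a repressor that growth hormone lowers, Fkbp5, Tsc22d3 and Zbtb16, which glucocorticoids induce, and Saa1 and Saa2 of the acute phase. Across the 20 mice, Idi1 and Sqle of cholesterol synthesis correlated (r = 0.949, rho = 0.947, both with permutation p = 1e-05, the smallest 100000 permutations can give). Without the 2 mice farthest from the median of Idi1, r was 0.934. Mt1 and Mt2 (r = 0.917, rho = 0.926, p = 1e-05 for both) and Saa1 and Saa2 (r = 0.929, rho = 0.938, p = 1e-05 for both) also correlated, with r = 0.906 and 0.898 without the 2 farthest mice. Related sequences in each pair can share probes. Fkbp5 followed Zbtb16 (r = 0.838, p = 0.0001, rho = 0.711, p = 0.00064, and 0.782 without the 2 farthest mice) and Tsc22d3 (r = 0.775, p = 0.00019, rho = 0.696, p = 0.00081, and 0.587). Col3a1 followed Col1a1 (r = 0.819, p = 4e-05, rho = 0.729, p = 0.00044, and 0.602), whereas Thrsp and Fasn did not pass (r = 0.339, p = 0.143, rho = 0.241, p = 0.305, and 0.205). Within HFD and within MSXH, r was 0.540 and 0.956 for Col3a1 with Col1a1, and 0.562 and 0.193 for Thrsp with Fasn. Over the 10 relations computed, the adjusted p was at most 0.00584 for the r of the 9 that passed and 0.0113 for rho.

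The wide spread of a few genes on the deposited scale is the third pattern. Compression that differs between probe sets was not tested as its source. Noise of single probe sets is argued against for the set as a whole. For 1000 genes drawn at random, the median correlation between probe sets of a gene was 0.390. That draw did not exclude the 50, was not matched for spread and used only probe sets above the filter, so the comparison is loose. Among the 50 genes, 27 had several probe sets, and over these the median correlation, with all probe sets used, was 0.953. It was above 0.6 for 19 of them and lower for Tsc22d3 (0.576), Socs2 (0.526) and Fkbp5 (0.168), whose correlations with other genes argue against such noise, as for Mt1 (0.527) unless Mt2 shares its probes, and for Scara5 (0.558), Car3 (0.450), Thrsp (0.258) and Hamp2 (0.0891), for which it stays open. Growth hormone signalling may have differed between mice at collection, as a hypothesis: Socs2 correlated with Cish (r = 0.795, permutation p = 4e-05, adjusted p = 6.67e-05, rho = 0.774, p = 7e-05), and with Onecut1 (r = 0.907, p = 1e-05, rho = 0.854, p = 1e-05), and negatively with Bcl6 (r = -0.601, p = 0.00526, rho = -0.565, p = 0.0102). Without the 2 mice farthest from the median of Socs2, r was 0.852, 0.905 and -0.449, and within HFD and within MSXH r with Cish was 0.763 and 0.824.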
